A study of Homo sapiens with 6 samples.

How the data were processed

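Messenger RNA was measured in 6 libraries of AC16 cells, a human cardiomyocyte cell line. Per the labels, 3 libraries came from untreated control cells and 3 from cells given 26 mM potassium chloride (KCl), all collected at 16 h. Per the labels' protocols, RNA was extracted with a column kit and made into strand-specific mRNA libraries for the DNBSEQ sequencer, and a sequencing company did the library work, the sequencing and the first analysis. The genome build was GRCh38.p12 per the submitters' processing notes. The aligner and the counting tool are not given in the sources used here.

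The deposited table lists 19386 genes with 3 kinds of value for each library. The first is an estimated count of reads per gene, which the authors deposited without normalization. Between 11.25% and 11.87% of these estimated counts in a library were not whole numbers. Such values can arise when reads that fit several genes or transcripts are shared out before the table is made. The second is TPM and the third is FPKM, both computed and deposited by the authors from gene length and library size. The table also holds the authors' group means of TPM and of the estimated counts. The columns carry short codes, and the codes were matched to control and KCl through these group means, which differed from the means of the library columns by at most 3.3e-10.

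Total estimated reads per library ran from 18601977 to 19286588. A count of 0 in a library allows up to 3 reads (95% limit), which is 0.156 to 0.161 CPM (reads scaled to the library total). Such limits cover counting error only, since molecular identifiers are not given in the sources used here. Replicate pairs of a group differed by more than sampling noise, with a chi-square per gene of 3.05 to 4.53, so no library was a copy of another. Spearman's correlation between replicates across genes was 0.984 to 0.985. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

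In the table, 27 gene symbols had been turned into dates and were restored from the gene ID, and 68 genes had a gene ID in place of a symbol and kept it. Of the gene IDs, 19061 matched the reference gene table used for names. No gene of the mitochondrial genome was among the genes analysed. A total of 725 genes had no read in any library. Chromosome positions, transcript lengths and GC content came from GENCODE release 29 on GRCh38, joined by gene ID.

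Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Libraries were scaled by TMM, genes with low counts were left out with filterByExpr (minimum count 10, minimum total 15), and KCl was compared with control by the two-sided quasi-likelihood F test with robust estimation. p-values were adjusted by the Benjamini-Hochberg method over the 13044 genes tested, with a threshold of 0.05. CPM values are scaled by TMM and are given as mean ± SD over n = 3 libraries. The standard error (SE) of a log2 fold change is its size divided by the square root of the F value. Positive log2 fold changes are higher in KCl.

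Before the data were examined, 33 gene lists were fixed. They covered NRF2 target genes, NRF2 pathway regulators, other antioxidant enzymes, metallothioneins, proteasome subunits, depolarization and calcium-response genes, hyperosmotic (NFAT5) response genes, ion pumps, channels and calcium handling, integrated stress response (ATF4) genes, unfolded protein response genes, heat shock genes, hypoxia-response genes, glycolysis enzymes, cholesterol synthesis genes, fatty acid synthesis genes and NF-kB and inflammatory genes. They also covered interferon-stimulated genes, p53 target genes, G1/S and replication genes, G2/M genes, cytosolic ribosomal proteins, nuclear-encoded respiratory chain subunits, mitochondrially encoded subunits, extracellular matrix genes, TGF-beta and YAP target genes, sarcomere and cardiac genes, autophagy and lysosome genes, the BCL2 family, and markers of fibroblasts, smooth muscle, endothelium, leukocytes and epithelium. A few genes stand in more than 1 list, such as SLC7A11, COL1A1, TAGLN, DES and BAX. Lists with at least 5 tested members entered the camera test of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 31 lists tested. The mitochondrially encoded subunits and the endothelium markers had too few tested members. The camera test with an estimated correlation and fry were run beside it.

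The genes named in the text were set by a rule fixed before the data were examined. It took the 10 higher and 10 lower genes with the largest log2 fold change among genes with a symbol, an adjusted p under 0.05, a mean log2 CPM of at least 1 and no overlap between the groups. It added from each list up to 3 members with the smallest p among those that passed, or 1 where none passed. It always included NFE2L2, KEAP1, HMOX1, NQO1, GCLC, GCLM, TXNRD1, SRXN1 and the most abundant member of each marker list. Other genes named as examples of a list were chosen after their values were seen, and they illustrate the counts. A few genes that the rule names are not reported here and are left out of the plots of single genes, but they stay in the counts and tests.

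The edgeR steps were tested on simulated counts for 13044 genes drawn from the real means and library sizes, with 200 genes changed in the comparison of KCl with control. The test recovered 58.5% of changes of 1.25-fold, 81% of changes of 1.5-fold and 89% of changes of 2-fold, with 6, 14 and 18 false calls. With the NRF2 target list raised 1.25-fold in simulated data, the camera adjusted p was 1.46e-49 with the preset correlation and 0.00201 with an estimated correlation, and 0 other lists were called. In the simulation, genes were drawn independently of each other and no gene outside the list changed. It therefore does not show how often camera calls lists falsely when genes are correlated or when many genes change.

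Alternatives fixed before the data were examined were RLE size factors, no filter on low counts, a mean count of at least 50, the replicate number as a block, leaving out each library in turn, DESeq2 1.42.0, limma-voom, limma on log2 FPKM or TPM with pseudocounts of 1 and 0.1, and glmTreat against a fold change of 1.2. Alternatives chosen after the data were seen were a GC correction per library, a transcript length correction per library, and a fit on genes whose estimated counts were all whole. The closing section gives their effect.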

Results

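Gene expression was measured by strand-specific mRNA sequencing in AC16 cells, a human cardiomyocyte line made by fusing cells of the adult ventricle with virus-transformed fibroblasts. There were 3 untreated control libraries and 3 libraries of cells given 26 mM KCl, collected at 16 h. Potassium chloride depolarizes the cell membrane and is the agent in cardioplegia solutions such as del Nido that stops the heart during surgery, and the study's title links it to NRF2 and oxidative stress. Library totals were 19257647, 19286588 and 18601977 estimated reads in control and 19159312, 18886525 and 19054751 in KCl. The translation factor gene EEF1A1 had the most reads in every library, and the 10 most abundant genes took 4.35% to 4.55% of the reads.

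The comparison of KCl with control asks which genes changed at this time, and in particular whether target genes of NRF2, the transcription factor that drives antioxidant genes, changed. Among the lists called higher after KCl with a preset correlation between genes were cholesterol synthesis (23 of 24 genes higher), fatty acid synthesis (8 of 11), NRF2 target genes (22 of 33, with 3 lower), hyperosmotic response genes (6 of 10, with 1 lower) and extracellular matrix genes (20 of 30, with 5 lower), and among those called lower were G2/M genes (18 of 25 lower) and p53 target genes (7 of 18 lower). Each list call was lost with an estimated correlation (camera adjusted p 0.15 to 0.32). Of 13044 genes tested, 2621 were higher and 2342 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). Most changes were small. The median size of a called log2 fold change was 0.31, and 130 genes rose and 88 fell by at least 2-fold. The groups did not overlap at 6241 of the 13044 tested genes, where chance gives 10%. They did not overlap at 4700 of the 4963 called genes, which were selected for a difference between the groups. The first principal component held 50% of the variance and separated the groups, with control libraries at -20.36 to -17.65 and KCl libraries at 17.42 to 20.77. The balance of higher and lower calls depended on the values and the test used. RLE size factors, which changed only the scaling of the counts, gave 52.4% higher calls. Higher calls made up 52.8% of the calls on TMM-scaled counts, but 33.3% by limma on log2(FPKM + 1), with 1594 higher and 3187 lower, and 41.1% by limma on log2(TPM + 1), with 1859 higher and 2659 lower. The median log2 fold change of all genes was -0.005 on counts, -0.055 on FPKM and -0.037 on TPM with the pseudocount of 1.

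Among genes that passed the test and had a symbol, a mean log2 CPM of at least 1 and no overlap between the groups, the largest rise was that of IL1RL1, which codes for the receptor of interleukin 33 (gene ID 9173, GRCh38 chromosome 2, 102311502 to 102352037). Its normalised read count went from 1.23 ± 0.18 CPM in control to 7.73 ± 0.455 CPM in KCl (mean ± SD, n = 3), a log2 fold change of 2.64 ± 0.19 (SE). DPT, a matrix protein gene, rose by 2.47 ± 0.24 from 0.906 CPM. The aldo-keto reductase genes AKR1C3 and AKR1C1, which lie near each other on chromosome 10 (5035354 to 5107686 and 4963253 to 4983283), rose by 2.24 ± 0.07 and 2.10 ± 0.10. TNFRSF11B, which codes for osteoprotegerin, rose by 1.93 ± 0.06, from 42.6 ± 0.82 to 162.7 ± 13.7 CPM. The amino acid transporter gene SLC38A4 rose by 1.80 ± 0.13. The placental alkaline phosphatase gene ALPP (2.07 ± 0.24), MYH15 (1.84 ± 0.27), LOC105374811 (1.74 ± 0.17) and IGSF10 (1.73 ± 0.23) completed the 10 largest rises. AKR1C1, AKR1C3 and ALPP have close relatives in the genome and estimated counts that were not whole, so their own shares of reads are uncertain.

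Among genes chosen in the same way, the largest fall was that of GPCPD1, a glycerophosphodiesterase gene (gene ID 56261, GRCh38 chromosome 20, 5544404 to 5611026), from 17.9 ± 0.456 to 4.49 ± 0.467 CPM, a log2 fold change of -1.99 ± 0.11. The next largest was that of the transporter gene SLC16A14 (-1.89 ± 0.16). The others of the 10 were SLC16A6 (-1.56 ± 0.20), SLC16A9 (-1.34 ± 0.20), SDSL (-1.57 ± 0.13), REXO5 (-1.52 ± 0.11), CCDC113 (-1.41 ± 0.14), PTPN22 (-1.32 ± 0.28), C11orf71 (-1.28 ± 0.26) and ENTPD5 (-1.25 ± 0.09). The edgeR adjusted p of these falls ran from 5.66e-13 for GPCPD1 to 0.000563 for PTPN22.

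**Figure D1:**
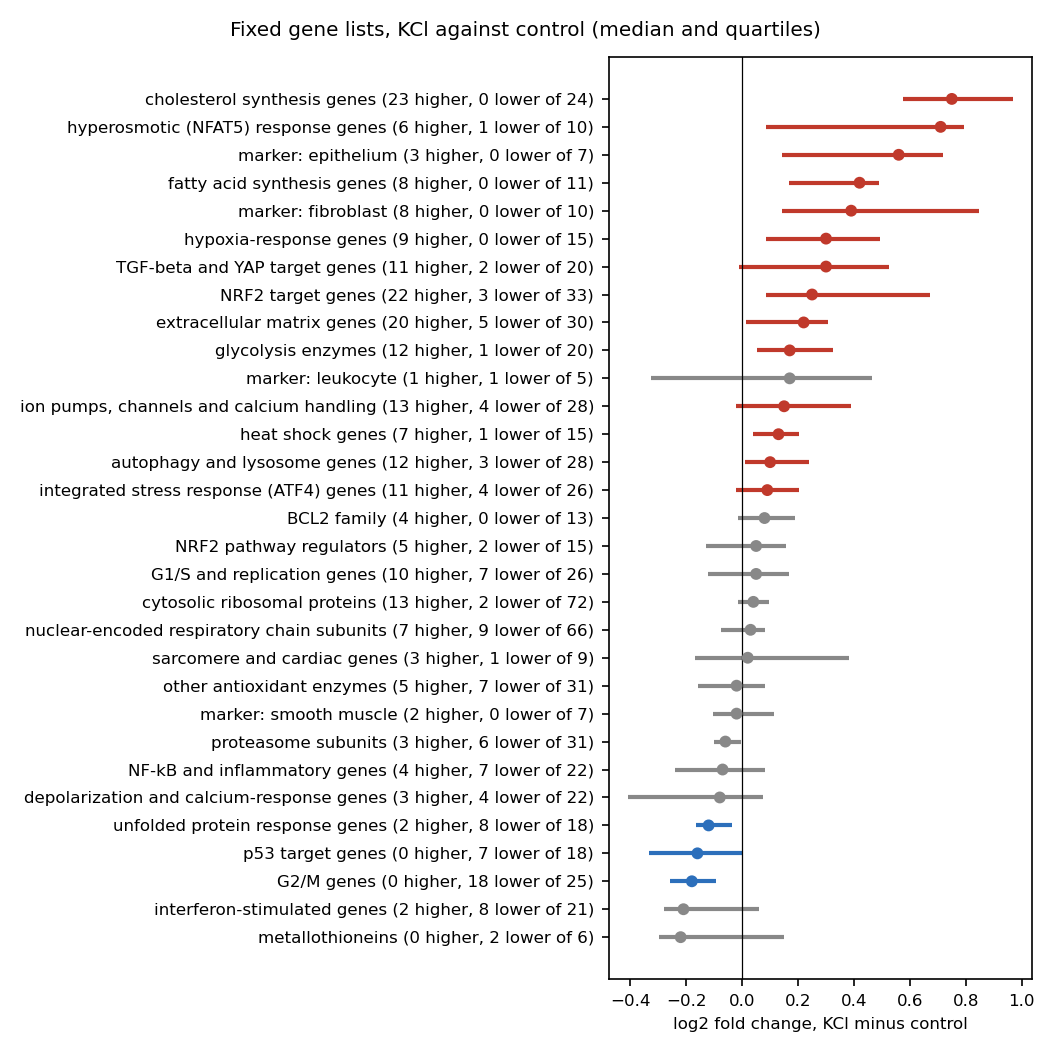
Each row is a gene list fixed before the data were examined, with the median (point) and quartiles (line) of its members' log2 fold changes, KCl minus control, on the horizontal axis. Red marks lists called higher and blue lists called lower by camera with the preset correlation, and grey the others. The cholesterol synthesis list has the highest median, 0.75.

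Of the 33 NRF2 target genes tested, 22 were higher and 3 lower after KCl, and 8 did not pass (23 higher and 3 lower when adjusted over the list alone). The list's median log2 fold change was 0.25. It was called higher by camera (adjusted p = 4.5e-07 with the preset correlation, adjusted p = 0.15 with an estimated correlation). NQO1, a quinone reductase gene (GRCh38 chromosome 16, 69706996 to 69726951), rose 1.84-fold from 283.4 ± 15.1 to 522.5 ± 19.2 CPM. TXNRD1, which codes for thioredoxin reductase (chromosome 12, 104215779 to 104350305), rose 1.84-fold from 596.5 ± 2.52 to 1097 ± 30.2 CPM. The peroxiredoxin gene PRDX1 rose by 0.69 on the log2 scale, and SLC7A11, the cystine transporter gene, by 0.67 ± 0.05. GCLM, the modifier subunit gene of glutamate-cysteine ligase, rose by 0.36 ± 0.06, and GCLC, the catalytic subunit gene, fell by 0.24 on the log2 scale (SE 0.08, edgeR adjusted p = 0.0143). SRXN1 rose by 0.20 ± 0.06 (edgeR adjusted p = 0.0116). The GCLC call was lost without control replicate 2 (adjusted p = 0.051) and without KCl replicate 3 (0.1), and the SRXN1 call without control replicate 3 (0.064) and without KCl replicate 3 (0.073), in the same edgeR test. Over all alternatives the adjusted p ran from 0.0085 to 1 for GCLC and from 0.0056 to 1 for SRXN1, with the highest from glmTreat. CBR3 (-0.47) and TALDO1 (-0.15) were the other lower members. The CBR3 call was lost without control replicate 2 (edgeR adjusted p = 0.067), KCl replicate 2 (0.096) or KCl replicate 3 (0.077), and the TALDO1 call without KCl replicate 3 (0.096) and with the length correction (0.086), so that 0 members were lower without KCl replicate 3. The heme oxygenase gene HMOX1 had 39.5 ± 3.39 CPM in control and 44.5 ± 1.91 CPM in KCl, and did not pass (log2 fold change 0.17 ± 0.07, edgeR adjusted p = 0.0517). Its call depended on the setting, with an adjusted p of 0.033 with the replicate number as a block and 0.046 by limma-voom, and a range of 0.017 to 1 over all alternatives. Against a fold change of 1.2 (glmTreat), 13 members were higher and 0 lower.

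The gene for NRF2 itself, NFE2L2 (chromosome 2, 177227595 to 177392697), was at 223.2 ± 6.8 CPM in control and 236.9 ± 12.1 CPM in KCl, with a log2 fold change of 0.09 ± 0.04 that did not pass (edgeR adjusted p = 0.127). Without KCl replicate 1 it passed, at 0.13 (edgeR adjusted p = 0.041, against a range of 0.041 to 1 over all alternatives). KEAP1, which codes for the protein that marks NRF2 for breakdown, had a log2 fold change of 0.05 ± 0.05 (edgeR adjusted p = 0.461). Of 15 NRF2 pathway regulators, 5 were higher and 2 lower, with the same counts adjusted over the list alone, and the list was not called (camera adjusted p = 0.52). BACH1, a repressor at NRF2 target sites, rose 1.76-fold from 51 ± 3.92 to 90 ± 3.7 CPM, MAFK, a small MAF partner, rose by 0.53 ± 0.06 and RBX1 by 0.36 ± 0.07 on the log2 scale. The 31 other antioxidant enzymes went both ways, with 5 higher and 7 lower (also adjusted over the list alone) and camera adjusted p = 0.6. Among them GLRX rose by 0.82 ± 0.07 and TXNRD2 by 0.65 ± 0.08, while TXNIP, which codes for a thioredoxin inhibitor, had a log2 fold change of -0.43 ± 0.04. Of 6 metallothionein genes 0 were higher and 2 lower (MT1E -0.49 ± 0.07, MT2A -0.16 ± 0.04; camera adjusted p = 0.34), and of 31 proteasome subunits 3 were higher and 6 lower (3 and 4 adjusted over the list alone; camera adjusted p = 0.18), with PSMD2 at 0.18, PSMA1 at -0.24 and PSMD4 at -0.17. Without KCl replicate 1 the proteasome list was called lower (camera adjusted p = 0.041, with a range of 0.041 to 0.77 over all alternatives), and without KCl replicate 3 the PSMD4 call was lost (edgeR adjusted p = 0.058).

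**Figure D2:**
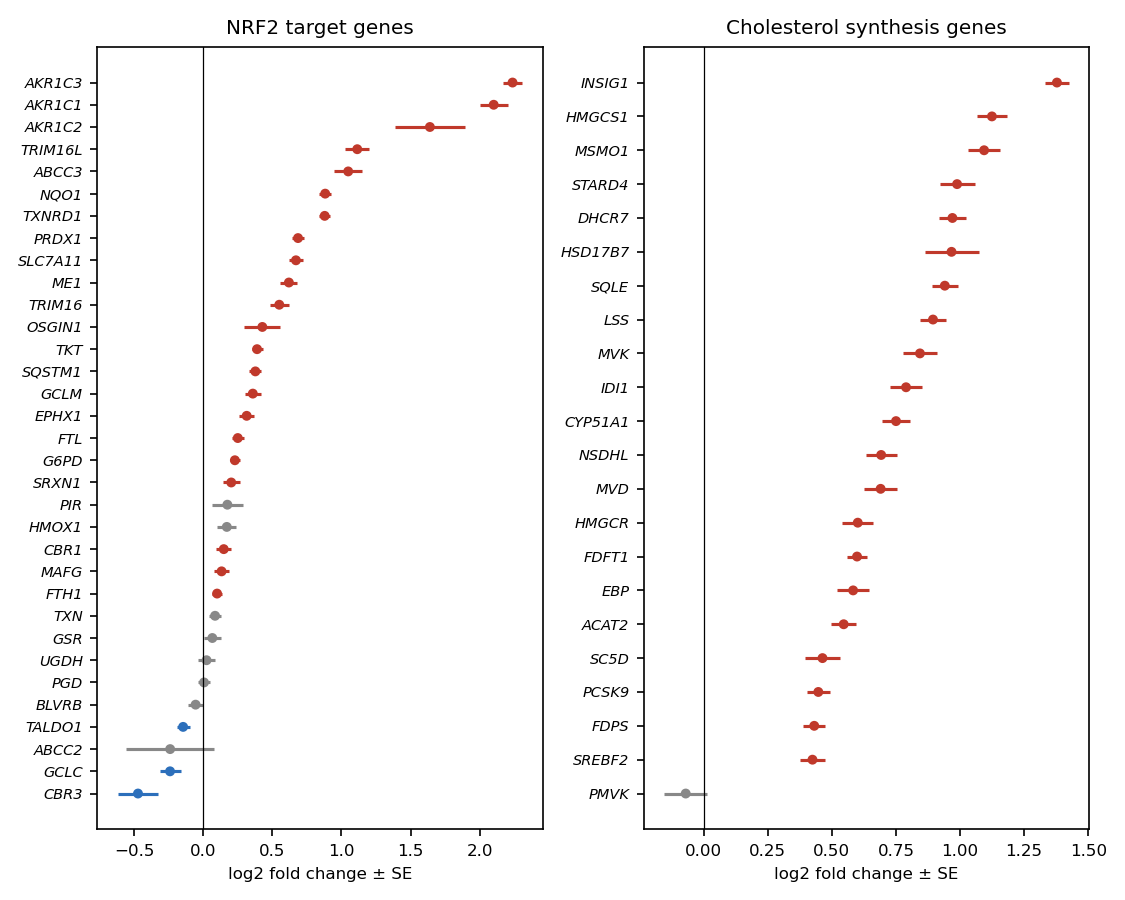
Log2 fold change, KCl minus control, with its SE (horizontal lines) for tested NRF2 target genes (left) and tested cholesterol synthesis genes (right) that are reported here, from 3 libraries per group. Red genes were called higher, blue genes lower, and grey genes did not pass. In the right panel PMVK, at -0.07, is the member that did not pass.

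Of 24 cholesterol synthesis genes tested, 23 were higher and 0 lower (the same adjusted over the list alone), with a median log2 fold change of 0.75. The camera adjusted p was 5.7e-16 with the preset correlation, and adjusted p = 0.15 with an estimated correlation. INSIG1, a sterol-responsive regulator of SREBP processing (chromosome 7, 155297776 to 155310235), rose 2.6-fold from 71.1 ± 0.776 to 184.7 ± 7.54 CPM. HMGCS1, which codes for an early enzyme of the pathway, rose by 1.12 ± 0.06 on the log2 scale. Of 11 fatty acid synthesis genes 8 were higher and 0 lower (the same adjusted over the list alone), with a median of 0.42. Their camera adjusted p was 0.00013 with the preset correlation, and adjusted p = 0.17 with an estimated correlation. FASN, the fatty acid synthase gene, rose 2.11-fold from 289.3 ± 20.7 to 609.5 ± 18.4 CPM, and the desaturase genes SCD and FADS2 rose by 0.79 ± 0.04 and 0.52 ± 0.04. SREBF2 rose by 0.42, and SREBF1 was at -0.02 and did not pass.

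Of 10 hyperosmotic response genes 6 were higher and 1 lower (the same adjusted over the list alone), with a median of 0.71. The camera adjusted p was 0.00033 with the preset correlation, and adjusted p = 0.15 with an estimated correlation. AKR1B1, the aldose reductase that makes sorbitol, rose 2.36-fold from 160.9 ± 4.14 to 379.6 ± 26.8 CPM, and SLC6A6, the taurine transporter gene, rose 2.34-fold from 20.1 ± 1.46 to 47 ± 3.39 CPM. SLC38A2, an amino acid transporter gene, rose by 0.68 ± 0.04 and SLC5A3, the myo-inositol transporter gene, by 0.75. HSPA4L was lower (-0.42), and NFAT5, the transcription factor of this response, had a log2 fold change of 0.13 that did not pass. The HSPA4L call was lost without control replicate 1 (edgeR adjusted p = 0.054), KCl replicate 1 (0.057) or KCl replicate 3 (0.1), and NFAT5 passed as higher without KCl replicate 3 (0.045). Of 28 genes of ion pumps, channels and calcium handling 13 were higher and 4 lower (the same adjusted over the list alone), with a median of 0.15. Their camera adjusted p was 0.013 with the preset correlation, and adjusted p = 0.17 with an estimated correlation. KCNK2, a background potassium channel gene, rose 1.98-fold from 17.8 ± 0.568 to 35.3 ± 1.51 CPM, and the sodium pump subunit gene ATP1B3 rose by 0.56 ± 0.05. Depolarization and calcium-response genes were not called as a list (camera adjusted p = 0.63), with 3 higher and 4 lower of 22 (the same adjusted over the list alone). BDNF rose by 0.51 ± 0.05 and PER1 by 0.63 ± 0.07, EGR1 was lower (-0.57 ± 0.07), and the immediate early gene FOS had a log2 fold change of -0.06 and did not pass. Changes before 16 h were not measured.

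**Figure D3:**
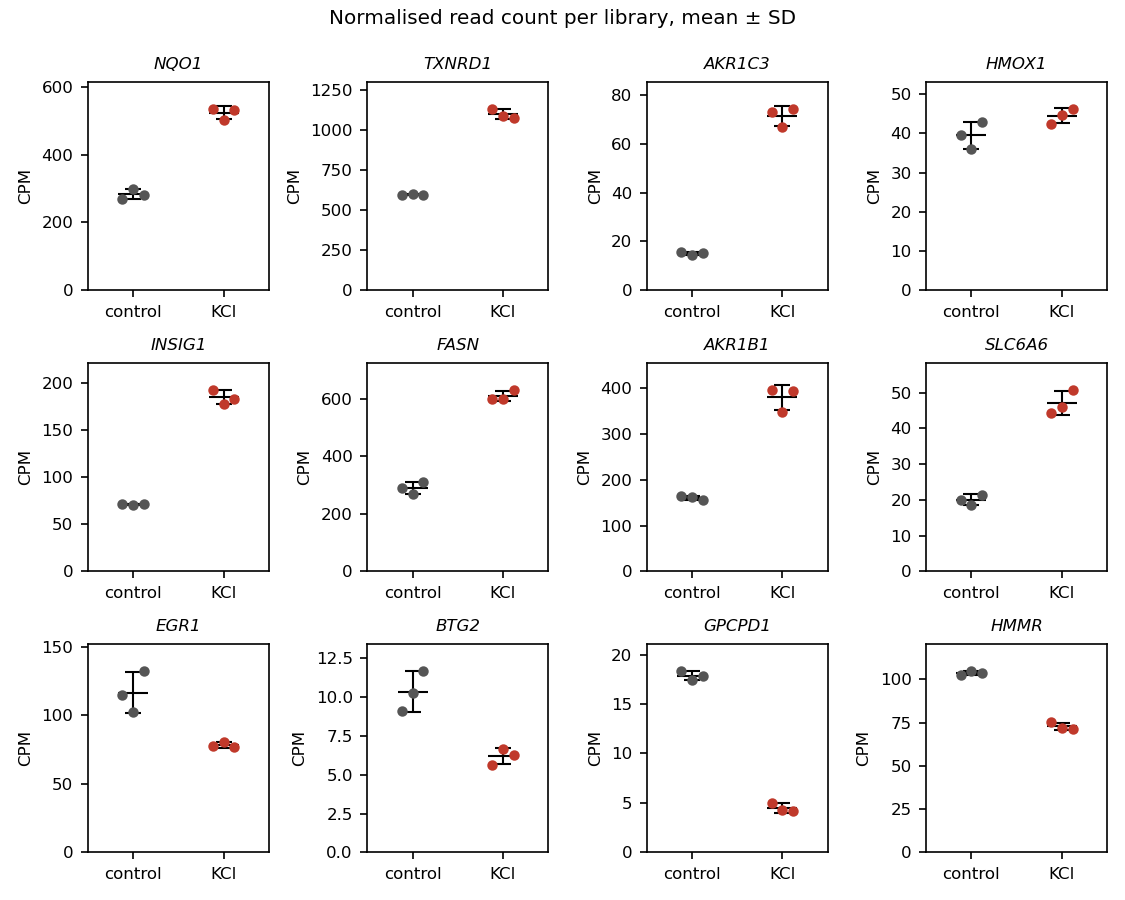
Normalised read count (CPM, vertical axes starting at 0) of 12 genes in each of the 3 control (grey) and 3 KCl (red) libraries, with the mean and SD in black. The groups overlap for HMOX1 and are apart for the other genes, such as NQO1 at a mean of 283.4 CPM in control and 522.5 CPM in KCl.

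Of 15 hypoxia-response genes 9 were higher and 0 lower (10 and 0 adjusted over the list alone), with a median of 0.30, camera adjusted p = 2e-04 with the preset correlation, and adjusted p = 0.2 with an estimated correlation. The vasodilator peptide gene ADM rose 2.04-fold from 52 ± 3.11 to 105.9 ± 12.2 CPM, and NDRG1 and the mitophagy receptor gene BNIP3 rose by 0.77 ± 0.05 and 0.57 ± 0.05, while VEGFA was at 0.02 and did not pass. Of 20 glycolysis genes 12 were higher and 1 lower (the same adjusted over the list alone), with a median of 0.17, camera adjusted p = 0.00043 with the preset correlation, and adjusted p = 0.2 with an estimated correlation. LDHA rose by 0.55 ± 0.04, the lactate exporter gene SLC16A3 by 0.58 ± 0.04 and PKM by 0.37 ± 0.04. The 66 nuclear-encoded respiratory chain subunits were not called (7 higher, 9 lower, and 4 and 8 adjusted over the list alone; camera adjusted p = 0.84), with NDUFB10 at -0.38, NDUFV1 at -0.26 and NDUFA7 at -0.31.

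Of 18 unfolded protein response genes 2 were higher and 8 lower (the same adjusted over the list alone), with a median of -0.12, camera adjusted p = 0.014 with the preset correlation, and adjusted p = 0.27 with an estimated correlation. The chaperone genes of the endoplasmic reticulum HYOU1 (-0.41 ± 0.04), PDIA4 (-0.43 ± 0.04) and CALR (-0.33 ± 0.04) were lower. Of 26 ATF4 genes of the integrated stress response 11 were higher and 4 lower (13 and 4 adjusted over the list alone), with a median of 0.09, camera adjusted p = 0.044 with the preset correlation, and adjusted p = 0.32 with an estimated correlation. STC2 rose by 0.42 ± 0.04, while SESN2 was lower (-0.47 ± 0.04). The ATF4 call was lost without control replicate 1 (camera adjusted p = 0.066), control replicate 3 (0.091) or KCl replicate 1 (0.083). It was also lost with the replicate number as a block (camera adjusted p = 0.066), at a mean count of at least 50 (0.056) and with the GC correction (0.067). Its camera adjusted p ranged from 0.0029 to 0.32 over all alternatives. Of 15 heat shock genes 7 were higher and 1 lower (the same adjusted over the list alone), with a median of 0.13, camera adjusted p = 0.029 with the preset correlation, and adjusted p = 0.22 with an estimated correlation. DNAJA1 rose by 0.31 ± 0.05, HSPH1 by 0.26 ± 0.05 and HSPB1 by 0.17 ± 0.04. The near-identical copies HSPA1A (0.23) and HSPA1B (-0.23) may share reads, and their own changes are uncertain. The heat shock call was lost without control replicate 3 (camera adjusted p = 0.055) or KCl replicate 1 (0.061), with a range of 0.0055 to 0.22 over all alternatives. Of 28 autophagy and lysosome genes 12 were higher and 3 lower (13 and 3 adjusted over the list alone), with a median of 0.10, camera adjusted p = 0.014 with the preset correlation, and adjusted p = 0.28 with an estimated correlation. NPC1 and NPC2, which carry cholesterol out of lysosomes, rose by 0.46 ± 0.05 and 0.36 ± 0.05, and GABARAPL1 by 0.57 ± 0.06.

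Of 25 G2/M genes 0 were higher and 18 lower (the same adjusted over the list alone), with a median of -0.18. The camera adjusted p was 2.5e-05 with the preset correlation, and adjusted p = 0.15 with an estimated correlation. HMMR went from 103.6 ± 1.19 to 72.9 ± 2.03 CPM (log2 fold change -0.51 ± 0.05), UBE2C was at -0.36 ± 0.04 and the cyclin gene CCNA2 at -0.37 ± 0.05, while the proliferation marker MKI67 was at -0.07 and did not pass. MKI67 passed as lower without KCl replicate 2 (edgeR adjusted p = 0.022) and with the length correction (0.0083). The 26 G1/S and replication genes went both ways, with 10 higher and 7 lower (11 and 7 adjusted over the list alone; camera adjusted p = 0.43). MCM5 rose by 0.42 ± 0.04 and MCM4 by 0.32 ± 0.04, and CCNE2 was lower (-0.64 ± 0.07). Of 18 p53 target genes 0 were higher and 7 lower (the same adjusted over the list alone), with a median of -0.16, camera adjusted p = 0.018 with the preset correlation, and adjusted p = 0.17 with an estimated correlation. BTG2 (-0.74 ± 0.13), MDM2 (-0.36 ± 0.06) and FDXR (-0.44 ± 0.09) were lower. The BCL2 family was not called (4 higher and 0 lower of 13, the same adjusted over the list alone; camera adjusted p = 0.14), with BOK at 0.37, BID at 0.38 and BMF at 0.82. Of 72 cytosolic ribosomal protein genes 13 were higher and 2 lower (11 and 1 adjusted over the list alone; camera adjusted p = 0.14), with RPL7A, RPL22 and RPL15 at 0.23, 0.20 and 0.17. The ribosomal list was called higher without control replicate 2 (camera adjusted p = 0.0068) or KCl replicate 3 (0.05), with a range of 0.0068 to 0.81 over all alternatives. Its counts depended on the setting too, with 24 higher and 0 lower without control replicate 2, 7 higher without control replicate 3, 20 higher with the replicate number as a block, 24 higher and 0 lower with the length correction, 2 higher and 6 lower on log2(FPKM + 1) and 6 higher and 6 lower on log2(TPM + 1).

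Inflammatory genes were not called as lists. Of 22 NF-kB and inflammatory genes 4 were higher and 7 lower (the same adjusted over the list alone; camera adjusted p = 0.27). CCL2, a monocyte chemokine gene, rose by 0.76 ± 0.05, and NFKB1 (-0.44 ± 0.06) and LIF (-0.37 ± 0.07) were lower. Of 21 interferon-stimulated genes 2 were higher and 8 lower (the same adjusted over the list alone; camera adjusted p = 0.069), with OAS2 at -0.78 ± 0.15, IFIT2 at -0.41 ± 0.07 and IFI6 at -0.27 ± 0.07. No member was higher without control replicate 2, control replicate 3 or KCl replicate 1, or on log2(FPKM + 0.1) or log2(TPM + 0.1), and 1 was higher without KCl replicate 2 or 3, by DESeq2 and on log2(FPKM + 1) or log2(TPM + 1). The interferon list was called lower without a filter on low counts (camera adjusted p = 0.027) and without control replicate 2 (0.032), without control replicate 3 (0.024), without KCl replicate 1 (0.046) or without KCl replicate 3 (0.05), with a range of 0.024 to 0.65 over all alternatives.

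Of 30 extracellular matrix genes 20 were higher and 5 lower (21 and 5 adjusted over the list alone), with a median of 0.22, camera adjusted p = 0.00033 with the preset correlation, and adjusted p = 0.32 with an estimated correlation. TIMP3, a metalloproteinase inhibitor gene, rose 2.26-fold from 471.4 ± 19.7 to 1064 ± 28.7 CPM. THBS1, the thrombospondin 1 gene, rose 2.17-fold and TNC, the tenascin C gene, 1.56-fold. Of 20 TGF-beta and YAP target genes 11 were higher and 2 lower (12 and 2 adjusted over the list alone), with a median of 0.30, camera adjusted p = 0.0029 with the preset correlation, and adjusted p = 0.2 with an estimated correlation. CTGF, a matricellular protein gene, rose 1.83-fold from 159.8 ± 6.3 to 292.9 ± 11.7 CPM, and AJUBA rose 1.41-fold. Of 10 fibroblast markers tested 8 were higher and 0 lower (the same adjusted over the list alone), with a median of 0.39, camera adjusted p = 0.00027 with the preset correlation, and adjusted p = 0.15 with an estimated correlation. PDGFRB rose 1.86-fold, LUM 1.96-fold and DCN 1.5-fold, while the most abundant, COL1A1, was at 4124 ± 157.6 CPM in control and 3937 ± 132.2 CPM in KCl and did not pass (log2 fold change -0.07 ± 0.04). It passed as lower on log2(FPKM + 1) (-0.15, adjusted p = 0.02), log2(FPKM + 0.1) (0.019) and log2(TPM + 0.1) (0.05) and with the length correction (-0.1, adjusted p = 0.013), with a range of 0.013 to 1 over all alternatives.

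Of 7 epithelium markers 3 were higher and 0 lower (4 and 0 adjusted over the list alone), with a median of 0.56, camera adjusted p = 0.013 with the preset correlation, and adjusted p = 0.17 with an estimated correlation. The most abundant, KRT18, rose 1.53-fold from 217.3 ± 5.77 to 333.2 ± 10.4 CPM. CDH1 rose from 0.704 ± 0.122 to 2.2 ± 0.644 CPM, and ESRP1 rose from 0.841 ± 0.12 to 1.49 ± 0.272 CPM (edgeR adjusted p = 0.0455). The ESRP1 call was lost without each control replicate in turn and without KCl replicate 1 or 2 (edgeR adjusted p 0.065 to 0.17), and with the replicate number as a block (0.055). It was also lost without a filter on low counts (edgeR adjusted p = 0.079) and by DESeq2 (0.11). By limma it was lost on log2(FPKM + 1) (0.069), log2(FPKM + 0.1) (0.06), log2(TPM + 1) (0.06) and log2(TPM + 0.1) (0.059). Its adjusted p ran from 0.039 to 0.21 over all alternatives. The list's call was lost without KCl replicate 2 (camera adjusted p = 0.05, with a range of 0.00025 to 0.17 over all alternatives). Smooth muscle markers were not called (2 higher and 0 lower of 7, the same adjusted over the list alone; camera adjusted p = 0.63). MYOCD rose by 1.12 ± 0.16 and SMTN by 0.23 ± 0.05, TAGLN was at -0.06, and the list's median of -0.02 had the opposite sign to the direction of its test. Leukocyte markers were not called (1 higher and 1 lower of 5, the same adjusted over the list alone; camera adjusted p = 0.9), with CD14 higher (0.94 ± 0.24) and CD68 lower (-0.47 ± 0.05). Of the endothelium markers, PECAM1 rose from 0.532 ± 0.11 to 1.47 ± 0.159 CPM and EGFL7 was at -0.26 and did not pass. EGFL7 passed as lower on log2(FPKM + 1) (adjusted p = 0.0064), log2(FPKM + 0.1) (0.0061), log2(TPM + 1) (0.0087) and log2(TPM + 0.1) (0.0085), with the GC correction (0.034) and on genes with whole estimated counts (0.049), with a range of 0.0061 to 0.91 over all alternatives.

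Few genes of the sarcomere and cardiac list were expressed at a level that could be tested. Of the 29 sarcomere and cardiac genes in the table, 20 were below the filter on low counts in these cells. TNNT2, MYL7, NPPA and NKX2-5, which were singled out after their values were seen, had 0 reads in every library, which allows up to 0.161 CPM in the shallowest. Of the 9 tested, 3 were higher and 1 lower (the same adjusted over the list alone; camera adjusted p = 0.49). GJA1, the connexin 43 gene, rose by 0.51 ± 0.05, GATA6 by 0.49 ± 0.05 and NEXN by 0.24 ± 0.07, and HAND2 was lower (-0.61, edgeR adjusted p = 0.04). The HAND2 call was lost without each control replicate in turn and without KCl replicate 1 or 2 (edgeR adjusted p 0.05 to 0.19) and by DESeq2 (0.083), and HAND2 was not tested at a mean count of at least 50.

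With the preset correlation, camera called 14 lists higher and 3 lower of 31. With an estimated correlation it called 0, although 9 lists had an unadjusted p under 0.05, and fry, which does not compare a list with other genes, called 21. The medians of the 17 called lists kept their sign under each gene-wise setting in which at least 5 members were tested, but some moved by over 1.5 times. The heat shock median went from 0.13 to 0.07 without control replicate 2 or KCl replicate 3 and to 0.08 on log2(FPKM + 1), and the epithelium median from 0.56 to 0.36 without KCl replicate 3, 0.18 on log2(FPKM + 1) and 0.31 on log2(TPM + 1). The median of ion pumps, channels and calcium handling went from 0.15 to 0.05 on log2(FPKM + 1), 0.08 on log2(FPKM + 0.1) and 0.09 on log2(TPM + 1), and that of autophagy and lysosome genes from 0.10 to 0.02 on FPKM with either pseudocount, 0.04 on log2(TPM + 1) and 0.05 on log2(TPM + 0.1). On FPKM with either pseudocount the ATF4 median went from 0.09 to 0.03 and the glycolysis median from 0.17 to 0.10, and on log2(FPKM + 0.1) the unfolded protein response median went from -0.12 to -0.19. On genes with whole estimated counts the NRF2 target median went from 0.25 to 0.16 and the ATF4 median to 0.05.

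Several counts of called members also moved by over 1.5 times under gene-wise settings other than glmTreat. On FPKM with either pseudocount, 3 heat shock and 7 ATF4 genes were higher, and 13 interferon-stimulated, 13 proteasome, 15 respiratory chain and 7 depolarization and calcium-response genes were lower. Higher members of the list of ion pumps, channels and calcium handling numbered 7 on log2(FPKM + 1) and 8 on log2(FPKM + 0.1) and on TPM with either pseudocount, and lower members 0 without control replicate 1 or KCl replicate 3. Respiratory chain subunits higher ranged from 1 on FPKM to 14 with the length correction. Lower proteasome subunits numbered 3 without control replicate 2 or KCl replicate 3 and 10 on TPM, and lower interferon-stimulated genes 4 without control replicate 1. Lower members of the other antioxidant enzymes ranged from 5 to 11 and higher members from 3 to 7. Lower extracellular matrix genes numbered 3 without control replicate 1, and lower ATF4 genes 2 without KCl replicate 1. Higher proteasome subunits numbered 1 without control replicate 1 and on FPKM and TPM with either pseudocount. Higher unfolded protein response genes numbered 1 without control replicate 1 or KCl replicate 2 and on FPKM and TPM with either pseudocount. On FPKM with either pseudocount, 4 NRF2 pathway regulators and 2 glycolysis genes were lower and 1 smooth muscle marker was higher, and 1 fibroblast marker was lower there, on log2(TPM + 0.1) and with the length correction. Lower heat shock genes numbered 0 without control replicate 1, KCl replicate 1 or KCl replicate 2 and on whole-count genes. Counts also moved by 1 gene for lower hypoxia-response genes (1 without control replicate 3), higher p53 target genes (1 without control replicate 2 and with the length correction) and lower sarcomere and cardiac genes (2 with the length correction).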

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

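Except for the alternatives called added, the alternatives were planned before the data were examined, and no named gene or list that was called changed direction under any of them. The 4963 calls stayed within 1.5 times under RLE, other filters, DESeq2 (2314 higher, 1999 lower), limma-voom, TPM values and the added GC, length and whole-count alternatives. Leaving out 1 library gave 4093 to 4560 calls. On FPKM, 1594 genes were higher with either pseudocount. FPKM values were not scaled by TMM, whose mean factor was 1.022 in control and 0.979 in KCl. Leaving out these factors lowers KCl values relative to control. The median log2 fold change of all genes was -0.069 on log2(FPKM + 0.1), against -0.005 on TMM-scaled counts. How much of the change in calls came from this was not tested. On FPKM, HSPB1, NEXN, RPL15, SMTN, SRXN1 and ESRP1 lost their calls, and COL1A1 and EGFL7 gained calls as lower. Testing against a fold change of 1.2, which by construction drops small changes, left 661 genes higher and 430 lower, and 13 NRF2 target genes higher and 0 lower. On genes with whole estimated counts, 24 NRF2 target genes were tested, not 33. Of these 13 were higher and 3 lower, against 22 and 3 in the main fit, and the median was 0.16, against 0.25. The rise thus rested in part on members with counts that were not whole, such as NQO1, GCLM and SLC7A11. Leaving out 1 library gave 0 to 3 NRF2 target genes lower, with 0 without KCl replicate 3 and 1 without control replicate 2, and 3 to 5 lists called lower, with 5 without KCl replicate 1. With an estimated correlation, camera called 0 lists higher and 0 lower, against 14 and 3 with the preset one. For the hyperosmotic, p53, ion pump and epithelium lists the estimated correlation (0.008, -0.011, -0.012 and -0.055) was below the preset 0.01. Their unadjusted camera p still rose, such as from 8.4e-05 to 0.017 for the hyperosmotic list. A higher correlation between genes thus does not account for the lost calls of these lists. With an estimated correlation, camera also takes its degrees of freedom from the residuals of the libraries (4), which raises p for the same statistic. How much of the losses came from this was not tested. On whole-count genes the ATF4 (camera adjusted p 0.2), p53 (0.054) and autophagy lists (0.061) lost their calls with fewer members tested.

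Whether replicate numbers pair the samples was not settled. Same-numbered libraries had correlations of deviations of -0.004, -0.006 and 0.048, and of the replicates only number 3 correlated best with its own number. The second principal component (14.3% of the variance) fell from replicate 1 to 3 in both groups. Its values were 10.83, 7.43 and -19.78 in control and 5.82, 1.85 and -6.16 in KCl. With the replicate block 2715 genes were higher and 2425 lower, 23 NRF2 target genes higher and 3 lower, and 13 lists called higher and 3 lower. ESRP1 and the ATF4 list lost and HMOX1 gained a call. CDH1, ESRP1 and PECAM1 had a mean of under 1 CPM in control, and whether depth limits such weak genes was not tested. ESRP1 lost its call under many alternatives. CDH1 and PECAM1 kept theirs in each gene-wise alternative that tested them (highest adjusted p 0.0082 and 0.021).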

Other observations

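The genes and families in this and the next paragraph were chosen after the data were seen. The SLC16A family of monocarboxylate and related transporters split after KCl, with 5 members higher and 3 lower of 12 tested. SLC16A14, SLC16A6 and SLC16A9 were among the 10 largest falls of genes with a symbol, an adjusted p under 0.05, a mean log2 CPM of at least 1 and no overlap between the groups, while SLC16A12 rose by 0.90 ± 0.27 (SE, n = 3 libraries per group) and SLC16A3 by 0.58 ± 0.04, and SLC16A1 was at 0.08 and did not pass. Of 10 ABC transporter genes of the A class 3 were higher and 2 lower, and the family was not called (camera adjusted p = 0.56 with the preset correlation, adjusted p = 0.93 with an estimated correlation). ABCA6, ABCA10 and ABCA9 rose by 1.56 ± 0.14, 0.98 ± 0.11 and 0.80 ± 0.24 (the ABCA9 call was lost without KCl replicate 2, edgeR adjusted p = 0.05), and ABCA1, the cholesterol efflux pump gene, had a log2 fold change of -0.88 ± 0.12, from 12.7 ± 1.08 to 6.89 ± 0.662 CPM.

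Gene families defined by the stem of the symbol were tested with camera, 161 in all. With the preset correlation 1 family was called, and 23 had an unadjusted p under 0.05. With an estimated correlation 0 were called, 3 had an unadjusted p under 0.05 and the smallest adjusted p was 0.85. The called family was that of the aldehyde dehydrogenases, with 0 members higher and 8 lower of 14 (camera adjusted p = 0.045 with the preset correlation, adjusted p = 0.85 with an estimated correlation). ALDH5A1 was at -0.94 ± 0.22 and ALDH16A1 at -0.47 ± 0.07 on the log2 scale. Families that did not pass included the intraflagellar transport genes (1 higher, 7 lower of 14, camera adjusted p = 0.1), the integrin alpha chains (5 higher, 0 lower of 11, camera adjusted p = 0.055) and the Krüppel-like factors (9 higher, 2 lower of 14, camera adjusted p = 0.1).

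Some genes had 0 reads in a library beside 50 or more in another library of the same group. The 3 tests of shared reads in this paragraph were chosen after the values were seen. Among genes with estimated counts that were not whole, 14 of 2591 had such a gap, against 0 of 9155 genes with whole counts (Fisher's exact test, two-sided, p = 6.28e-10). SULT1A3 had 230.4 and 237 estimated reads in control replicates 1 and 2 and 0 in the other libraries, and its near-identical copy SULT1A4 had reads in exactly those other libraries. The summed CPM of the pair differed by -0.153 on the log2 scale (95% interval -0.59 to 0.28). HSPA1A and HSPA1B had no such gap and were picked after HSPA1A was seen to be higher and HSPA1B lower. Their summed CPM differed by -0.062 (-0.25 to 0.13), which decides little, since opposite changes cancel in a sum. The gaps could come from reads being shared out between near-identical or overlapping genes before the table was made. No biological explanation was tested.

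The rise of NRF2 target genes could come from reads shared within the AKR1C genes or from GC content or transcript length bias. The corrections for GC and length and the random lists were chosen after the data were seen. Without AKR1C1, AKR1C2 and AKR1C3 the list was still called higher (30 tested, 19 higher, 3 lower, median 0.22, unadjusted camera p = 1e-06 with the preset correlation), which argues against the AKR1C genes as the whole source. With an estimated correlation the unadjusted p was 0.016 without them and 0.017 with them, and the latter became 0.15 after adjustment over the lists. On genes with whole estimated counts only, the list kept its call with the preset correlation, but 13 members were higher and the median was 0.16. Reads shared by members outside the AKR1C genes thus remain open as a part of the rise. With a transcript length correction 23 members were higher, against 22 without, and the list's median went from 0.25 to 0.29. The correction moved no member by more than 0.06, near the members' median SE (0.056), so this count decides little. The correlation across genes of log2 fold change with length went from 0.116 to 0.001, which follows from the correction itself. Among 10000 random lists matched on transcript length, the upper end of the central 95% range was 0.09. The list's median lay at percentile 100 of them, which argues against length as the whole source. A GC correction left 23 members higher, but it moved no tested gene by more than 0.03, less than the median SE of the members (0.056), and so decides little. Among 10000 random lists matched on GC content, the upper end of whose central 95% range was 0.1, the list's median of 0.25 lay at percentile 100, which argues against GC content as the whole source. Whether the activity of the NRF2 protein rose after KCl was not tested. A measure of NRF2 protein in the nucleus, or KCl given to cells without NFE2L2, would test it.

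The rise of hyperosmotic response genes may reflect the osmotic strength of the added salt instead of potassium or depolarization. The random-list tests and the GC correction were chosen after the rise was seen. The list's median of 0.71 lay at percentile 100 of 10000 random lists matched on expression, whose 95th percentile was 0.15, which describes the rise and does not bear on its source. A GC correction left 6 members higher, but it moved no tested gene by more than 0.03 and so decides little. Among 10000 random lists matched on GC content, the upper end of whose central 95% range was 0.17, the median lay at percentile 100, which argues against GC content as the whole cause. Osmotic strength and potassium cannot be told apart, because the design holds no samples given another salt or solute at the same osmotic strength.

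The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split was the 1 split of 10 with a result as large for each of the 3 counts. It called 4963 genes, against 0 in the highest other split, 22 NRF2 target genes higher, against 0, and 17 lists, against 10. Splits that mix the groups keep part of the group difference, and the rest adds to the spread within their groups. Their count of 0 genes is thus no measure of the noise. In the 9 other splits, camera with the preset correlation called the cholesterol synthesis list 9 times and the NRF2 target and G2/M lists 5 times each. Of the lists that the real split did not call, it called the interferon list 5 times, the ribosomal list 4, the proteasome and respiratory chain lists 3 each, the NF-kB list 2 and the depolarization list 1. The smallest camera adjusted p in these splits was 1.1e-09 for the ribosomal, 2.4e-05 for the respiratory chain and 0.00011 for the proteasome list. The ribosomal value was below that of the NRF2 target list in the real split (4.5e-07). With the preset correlation, camera can thus give very small p-values to lists that the real split did not call. Of the 17 lists called in the real split, 4 were called in no other split and 14 had their smallest adjusted p in the real split.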
